A study of Homo sapiens with 3 samples.

How the data were processed

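Polyadenylation, strand and read layout of the RNA libraries are not given in the sources used here. The series holds 3 libraries of CP70 cells in 10% serum under puromycin at 2 ug/ml, 1 each for a hairpin against EGFP, EZH2 and E2F6, from stably selected clones. The series text calls the control a vector control, and the EZH2 hairpin sits in another vector backbone than the other 2. Values per gene are RPKM, reads per kilobase of gene model per mapped read total, computed by the authors per the file headers and used as deposited. The plan made before the files were opened had assumed FPKM. Genome build hg19 is given in the submitters' processing notes. The aligner, counting program and annotation are not given in the sources used here.

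Each file listed 57773 features, of which 16829, 16719 and 17913 were above 0 in shEGFP, shEZH2 and shE2F6, and the RPKM summed to 264557, 236941 and 251176. Because RPKM is a whole number of reads divided by length and library total, the totals were recovered from single-exon genes that held 1 read (14, 13 and 17 genes), which gave 9014980, 4871295 and 10230911 mapped reads. A length and whole read numbers were then sought for each feature that fitted all 3 libraries. All 19807 features above 0 in any library were recovered, and the recovered reads made up 80.6%, 80.2% and 81.4% of the totals. Of 16093 features with a reference length in GENCODE 29, 56.9% had that length and 78.9% lay within 5% of it. GENCODE 29 is built on GRCh38, so it served for lengths and names only and no coordinates were used. A further 2234 names carried a suffix for repeated names, 27 had turned into dates and 2 were duplicated, and a listed gene with several suffixed entries was taken from the one with the highest mean.

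Ratios were taken as log2(RPKM + 1) of one library over the other, among genes with at least 1 RPKM in 1 of the 2, and genes at least 2-fold apart on that scale were counted. Folds printed for single genes are plain RPKM ratios with exact 95% binomial intervals from the recovered reads (Clopper-Pearson, given the library totals). They are conditional on the recovered reads. A gene with 0 reads in 1 library is given as at least the fold against a floor of 3 reads there, which leaves out counting error of the other library, and the lower end of its interval is given beside it. With 1 library per group no test was run, and ratios compare these libraries, not conditions. Levels from counting error alone came from 100 sets of simulated unchanged libraries, Poisson draws at these depths around the pooled expression.

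Gene lists (40, with 1066 genes) were fixed before the files were opened. A list with at least 5 measured members stood apart where its median log2 ratio lay at or below percentile 2.5 or at or above 97.5 of 10000 random lists of the same size matched on mean expression in 20 bins. Of lists standing apart against shEGFP or between the knockdowns, 12 had members with 0 reads in 1 library, at most 5 each, and setting these to the floor moved a median by at most 0.0055. Genes were named by a rule fixed beforehand: the targeted genes and others named beforehand, with KIT, CD274 and miR-193a among them; the 8 largest ratios each way against shEGFP and the 5 each way between the knockdowns or shared by both, with at least 5 RPKM in the higher library and without small RNA genes; and up to 4 members of each list standing apart or 2 of each other list. Clone-based names and dates were not counted as gene symbols. Not every gene so selected is reported here. Genes outside the rule are said to be chosen or named after their values were seen.

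Near-identical copies share reads in ways that cannot be resolved here, which applies to PPIAP22, RPL15P3, HSPA1B, XCL1, KRT18, KRT8, FTL, FTH1, the lambda interferons, histone and HLA genes and the overlapping mitochondrial genes. Since the strand is not stated, overlapping antisense genes cannot be told apart.

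The procedure was tested on simulated data. All 3 library totals were recovered exactly, as were the reads of 97.1% of 3000 features and of 97.5% of those with at least 20 reads. Of 200 genes given a difference, all 100 at 4-fold were counted (100%) and 20% of the 100 at 2-fold, with 18 unchanged genes counted among 11269. Random lists stood apart in 4.5% of 200 cases, and a list shifted by 0.5 lay at percentile 100. Alternatives set beforehand (9) were a pseudocount of 0.1, no filter, a filter of 5 RPKM, scaling to a common sum, by median ratio and by upper quartile, omission of small RNA genes, a 4-fold threshold and unmatched random lists. Another 2, thinning of the reads to the shallowest library and counting only genes whose interval lay beyond 2-fold, were chosen after seeing the data. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.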

Results

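RNA was sequenced from CP70 cells, a human ovarian cancer line selected for resistance to cisplatin, that carried 1 of 3 short hairpin RNAs delivered by lentivirus and kept under puromycin at 2 ug/ml. The hairpins targeted EGFP, which these cells lack and which served as the control, the histone methyltransferase EZH2, or the transcriptional repressor E2F6. Each group was 1 library, so no value below has a replicate and no test between conditions was possible. The shEGFP, shEZH2 and shE2F6 libraries held 9014980, 4871295 and 10230911 mapped reads by a reconstruction from the deposited RPKM values. At least 1 RPKM was reached by 10692 features in shEGFP, 11079 in shEZH2 and 10886 in shE2F6. Ratios between libraries are given with exact 95% binomial intervals of the recovered reads in parentheses. These intervals cover counting error only and say nothing of how much separate cultures differ.

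The targeted genes check the labels. E2F6 RNA stood at 4.67 RPKM in shEGFP, 6.22 in shEZH2 and 1.76 in shE2F6, so that it was 2.66-fold lower (2.01 to 3.55) in the library meant to lose it and 1.33-fold higher (1.05 to 1.69) in shEZH2. EZH2, the catalytic subunit of Polycomb repressive complex 2 (PRC2), stood at 12.6 RPKM in shEGFP, 9.22 in shEZH2 and 21.9 in shE2F6. It was only 1.37-fold lower (1.16 to 1.62) in shEZH2 than in shEGFP, and 1.74-fold higher (1.56 to 1.94) in shE2F6. Both genes thus went in the direction of their labels, EZH2 by a small margin.

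**Figure D1:**
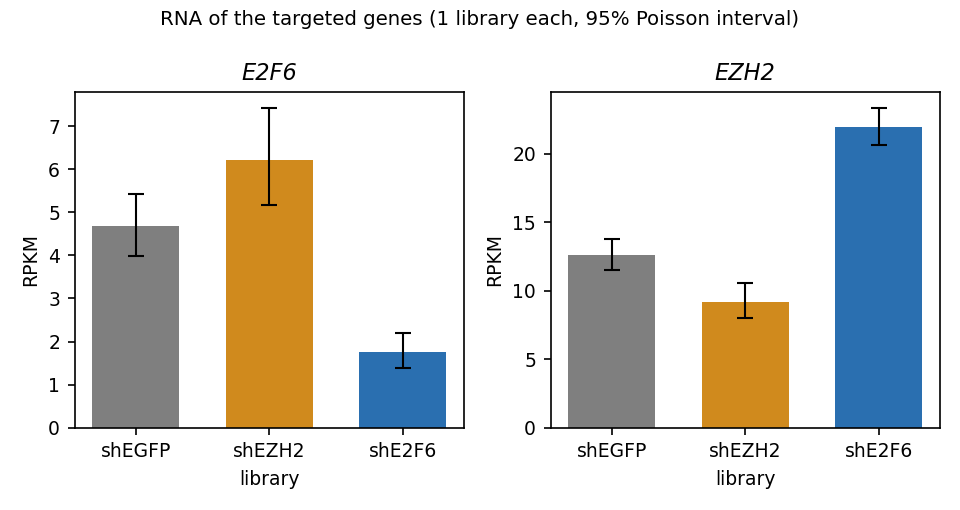
RPKM (vertical axes, from 0) of E2F6 and EZH2 in the shEGFP, shEZH2 and shE2F6 libraries (horizontal axes), 1 library per bar, with exact 95% Poisson intervals of the reads as error bars. E2F6 is lowest in shE2F6 at 1.76 RPKM, and EZH2 is lowest in shEZH2 at 9.22 RPKM and highest in shE2F6 at 21.9 RPKM.

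The study's title places E2F6 and EZH2 around the silencing of the microRNA miR-193a, stem-like traits and escape from immunity. The receptor tyrosine kinase gene KIT and MIR193A, the row of the microRNA gene, were listed at 0 in all 3 libraries. The 0 of MIR193A was not taken as absence of the mature microRNA. Of 7 study axis genes, these and others the title points to, only E2F6, EZH2 and CD274 reached 1 RPKM, with a median log2 ratio to shEGFP of 0.75 in shE2F6 and 0.35 in shEZH2. CD274, which encodes the immune checkpoint ligand PD-L1, was higher in both knockdown libraries, 4.41-fold (2.74 to 7.41) in shE2F6 and 5.46-fold (3.28 to 9.44) in shEZH2, from 0.567 RPKM in shEGFP.

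The shE2F6 and shEGFP libraries were compared to ask which RNAs accompany loss of E2F6. The shE2F6 library had higher levels of antiviral, inflammatory and stress genes, and lower levels of G1/S and cholesterol synthesis genes and of most, not all, measured mesenchymal and matrix genes. Among the 8 genes with the largest positive log2 ratios, the chemokine gene CCL5 had 1 read in shEGFP and 1554 in shE2F6, a 1369-fold ratio with a wide interval (245 to 54119). OASL, an interferon-induced antiviral gene, was 304-fold higher (147 to 757), and IFNL1, a type III interferon with 0 reads in shEGFP, was at least 78.1-fold higher against the floor of 3 reads (interval from 63.1). PHLDA1 was 150.4-fold higher (101 to 235), and KRT18, a simple-epithelium keratin, 108-fold (61.4 to 209). GCG, the proglucagon gene, was 72.6-fold higher (51.0 to 107), and TXNIP, an inhibitor of thioredoxin, was 53.6-fold higher (39.97 to 73.7).

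At the other end, SEMA6D, a semaphorin, was 116-fold lower (66.0 to 224) in shE2F6 than in shEGFP. NID1, a basement membrane protein gene, was 62.4-fold lower (47.3 to 84.0), and LOX, a collagen cross-linking enzyme gene, was 52.3-fold lower (37.3 to 75.8). CCND2, which encodes cyclin D2, stood at 236 RPKM in shEGFP and 6.49 in shE2F6, 36.3-fold lower (33.1 to 39.9). The chemokine gene XCL1 was 73.2-fold lower on 4 reads in shE2F6 (28.2 to 271). ZPLD1 was 20.4-fold lower (17.3 to 24.2), MAP2K6, a kinase of the p38 pathway, 19.6-fold (15.1 to 26.0), and LPHN2, an adhesion receptor gene, 12.0-fold (10.7 to 13.6).

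Among gene lists fixed before the data were examined, 21 of the 34 with at least 5 measured members stood apart from random lists of the same size and expression in this comparison, where 1.7 would for lists of unrelated genes. The fixed lists share members and hold genes regulated together, so differences between single cultures alone can set more of them apart than that. In 14 of them the median was higher and in 7 it was lower. Interferon response genes led: 40 of 43 measured members were higher in shE2F6, 32 of them at least 2-fold, with a median log2 ratio of 2.11. Of 16 leukocyte markers only CD68, 3.24-fold higher (2.58 to 4.12), and ITGAM reached 1 RPKM in shEGFP or shE2F6, and no endothelial or erythroid marker did. Interferon examples were RSAD2 at 162-fold (63.1 to 597), the RNA sensor gene IFIH1 at 91.4-fold (48.0 to 201), HERC5 at 43.9-fold (28.8 to 70.3) and BST2 at 42.0-fold (19.1 to 115). All 15 measured NF-kB and cytokine genes were higher, 14 at least 2-fold (median 1.73), including BIRC3 at 196-fold (89.8 to 535), CSF1 at 61.8-fold (28.2 to 169) and NFKBIA at 8.18-fold (6.94 to 9.70). Unfolded protein and amino acid stress genes had a median of 1.27, with 25 of 30 higher, among them ATF3 at 39.1-fold (30.7 to 50.6), TRIB3 at 16.2-fold (12.8 to 20.8) and CHAC1 at 15.1-fold (11.8 to 19.6).

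Of 25 listed epithelial genes only 7 were measured, and 6 of these were higher (median 1.24). The desmosome gene DSP was at 11.0-fold (8.39 to 14.6), from 0.637 RPKM in shEGFP. Replication-dependent histone genes had a median of 0.99 with 21 of 25 higher, HIST1H2BK at 5.26-fold (4.43 to 6.29) being one. Histone genes have near-identical copies, so how their reads were shared out is uncertain. The p53 target genes (median 0.47, 16 of 24 higher) included the cell cycle inhibitor CDKN1A at 49.8-fold (19.2 to 184) and GADD45A at 7.78-fold (6.75 to 8.997). Apoptosis genes (median 0.46, 19 of 23 higher) included PMAIP1 at 11.1-fold (8.83 to 14.1). Immune checkpoint and evasion genes (median 0.50, 13 of 18 higher) included ULBP1, a ligand of natural killer cell receptors with 0 reads in shEGFP, at least 89.3-fold higher against the floor (interval from 72.2), the adenosine-producing enzyme gene NT5E at 47.0-fold (15.8 to 230.3) and CD55 at 6.15-fold (5.03 to 7.59). Genes of KIT and receptor tyrosine kinase signalling (median 0.37, 15 of 25 higher) included FOSL1 at 11.9-fold (9.995 to 14.3), and immediate early and heat shock genes (median 0.35, 13 of 21 higher) included JUN at 4.37-fold (3.93 to 4.88). Estrogen response genes (median 0.43, 8 of 10 higher) included XBP1 at 4.72-fold (4.19 to 5.34).

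Other lists with a higher median were mixed. Ovarian cancer stem cell genes had a median of 0.57, yet 9 were higher and 8 lower: KLF4 was 202-fold higher on 2 reads in shEGFP (55.5 to 1671) and ALDH1A1, a stem cell marker enzyme, 10.4-fold higher (9.46 to 11.4), while TWIST1 was 8.82-fold lower (7.37 to 10.6) and NOTCH3 3.96-fold lower (3.51 to 4.47). Tumour suppressors silenced by PRC2 (median 0.39) held 10 higher and 8 lower genes, and developmental PRC2 targets (median 0.31) 13 and 10. In the latter, BARX1 was 10.2-fold higher (6.67 to 16.4) and HAND2 was 4.42-fold lower (3.89 to 5.03). Among the tumour suppressors 4 genes were at least 2-fold higher and 4 at least 2-fold lower. The higher ones were CDKN1A, CXCL10, NGFR and PSMB9, of which CDKN1A is also in the p53 list and PSMB9 in the antigen presentation list. With only genes of at least 5 RPKM, these PRC2 lists had medians of -0.20 and -0.46 instead.

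Lower in shE2F6 were mesenchymal and extracellular matrix genes (median -0.59, 16 of 26 lower), with ACTA2 11.4-fold lower (9.34 to 14.0), although THBS1 was 9.91-fold higher (8.53 to 11.6). Fibroblast markers, included as a check for other cells, were lower too (median -1.56, 4 of 5 lower), with COL6A3 at 8.17-fold lower (6.99 to 9.59), COL3A1 at 5.52-fold (5.19 to 5.87) and POSTN at 3.41-fold (2.93 to 3.97). These 3 are also in the mesenchymal list. The other measured markers were LUM, which was lower, and THY1, named after its values were seen, which was higher. E2F target genes of G1/S had a median of -0.32 with 33 of 42 lower, among them the checkpoint kinase gene CHEK1 at 2.05-fold (1.79 to 2.36); RRM2 was 1.81-fold higher (1.73 to 1.90). G2/M genes (median -0.17, 23 of 33 lower) included MKI67 at 1.79-fold lower (1.72 to 1.85). Cholesterol synthesis genes (median -0.46, 21 of 24 lower) included LSS at 3.28-fold lower (2.79 to 3.87) and FDPS at 2.18-fold lower (2.01 to 2.36). WNT and Notch pathway genes (median -0.24, 16 of 24 lower) included DKK1, a secreted WNT antagonist, at 6.49-fold lower (5.60 to 7.56). All 13 mitochondrially encoded genes were lower (median -0.36), and their reads made up 10.1% of mapped reads in shEGFP, 6.75% in shEZH2 and 7.92% in shE2F6.

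Lists close to E2F6 itself did not stand apart. PRC1.6 and E2F6 partner genes had a median of 0.10, PRC2 subunits 0.04, other PRC1 subunits, canonical and variant, 0.00, and 6 measured germline and meiosis genes known to be repressed by E2F6 or PRC1.6 a median of -0.03. One of those germline genes, CPEB1, was 10.8-fold higher (6.93 to 17.8), and the recombinase gene DMC1 was 4.69-fold lower (2.64 to 8.88). The only cancer testis antigen measured, PRAME, was 1.26-fold lower (1.11 to 1.44). Targets of miR-193a had a median of 0.07, HOX genes -0.28, antigen presentation genes 0.25, hypoxia and glycolysis genes 0.07, platinum resistance and DNA repair genes -0.16, nuclear oxidative phosphorylation genes -0.09, cytosolic ribosomal protein genes 0.06, chromatin modifier genes -0.09 and housekeeping genes 0.06. Within them, DNMT3B was 3.46-fold lower (2.83 to 4.25) and TET1 4.94-fold lower (3.91 to 6.30), whereas RYBP was 2.27-fold higher (2.01 to 2.57). These genes went the same way in shEZH2 against shEGFP. There DNMT3B was 3.34-fold lower (2.56 to 4.43), TET1 3.29-fold lower (2.51 to 4.36) and RYBP 1.95-fold higher (1.68 to 2.25). CPEB1 was 10.1-fold higher (6.33 to 17.0) and DMC1 2.79-fold lower (1.49 to 5.69) in shEZH2.

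In all, 846 of 11477 genes were at least 2-fold higher and 428 at least 2-fold lower in shE2F6 than in shEGFP on the log2(RPKM + 1) scale, and 219 and 55 passed 4-fold. Unchanged libraries of these depths, simulated 100 times with counting error only, gave at most 18 in either direction. The counts ran from 494 and 282 among genes of at least 5 RPKM to 1822 and 976 when the libraries were rescaled to the same, larger sum, and 15 of the 21 lists still stood apart without the filter on low values. The epithelial, stem cell, estrogen response, WNT and Notch, receptor tyrosine kinase and immediate early lists were lost there, and the G2/M list was lost with random lists not matched on expression. At 5 RPKM or more the tumour suppressor, developmental PRC2, stem cell and immediate early lists were lost and the epithelial and fibroblast lists were too small to judge, and with reads thinned to the shallowest library the tumour suppressor, developmental PRC2 and estrogen response lists were lost.

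The comparison of shEZH2 with shEGFP asks the same of EZH2, with the reservation that EZH2 RNA was lower by only 1.37-fold. The picture resembled that of shE2F6. Antiviral, inflammatory and stress genes were again higher, and G1/S and cholesterol synthesis genes lower. CCL5 was 1514-fold higher (271 to 59865) on 1 read in shEGFP, OASL 342-fold (165 to 852) and MMP1, a secreted collagenase gene, 163-fold (114 to 241). TXNIP was 110.3-fold higher (82.2 to 152) and VGF, a secreted neuropeptide precursor gene, 90.2-fold (59.2 to 145). PHLDA1 was 220.1-fold higher (148 to 344) and GCG 80.3-fold higher (56.3 to 119). The genes with the largest negative ratios were NID1 at 43.3-fold lower (31.0 to 62.3), LOX at 84.7-fold lower (45.9 to 177), CCND2 at 11.8-fold lower (10.9 to 12.7), SEMA6D at 31.5-fold lower (20.5 to 51.0), ACTA2 at 12.1-fold lower (9.05 to 16.4), BPGM at 11.4-fold lower (8.26 to 16.3) and TWIST1 at 8.52-fold lower (6.66 to 11.1). The processed pseudogene PPIAP22 also ranked there, on 2 reads in shEZH2, and shares its sequence with the abundant PPIA.

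Of 34 lists, 18 stood apart, 12 higher and 6 lower. Interferon response genes had a median of 2.27, with 42 of 43 higher and 35 at least 2-fold; RSAD2 reached 277-fold (108 to 1020.4) and IFIH1 108-fold (56.6 to 238). All 16 measured NF-kB and cytokine genes were higher (median 1.47), with LIF at 8.37-fold (7.67 to 9.15). Of the leukocyte markers only CD68 was measured, 4.65-fold higher (3.64 to 5.97). Unfolded protein and amino acid stress genes had a median of 1.36 and 26 of 30 higher, with SESN2 at 25.9-fold (21.6 to 31.2). All 7 measured epithelial genes, of 25 listed, were higher (median 1.44). KRT18 was at 138-fold (78.6 to 268), DSP at 18.2-fold (13.8 to 24.2) and EPCAM at 21.7-fold on 4 reads in shEGFP (7.95 to 83.1). Antigen presentation genes stood apart here (median 0.75, 13 of 18 higher), with HLA-B at 14.7-fold (12.0 to 18.3), TAP1 at 7.03-fold (5.18 to 9.67) and the immunoproteasome gene PSMB9 at 14.2-fold (6.04 to 40.7). In shE2F6 this list did not stand apart, with 10 members higher and 6 lower, but HLA-B was 10.5-fold higher there too (8.55 to 12.9). HLA class I genes have close paralogs that can share reads. Immune checkpoint and evasion genes had a median of 0.85 (16 of 19 higher), with NT5E at 105-fold on 3 reads in shEGFP (35.5 to 517).

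Histone genes (median 0.87, 20 of 26 higher), p53 targets (0.63, 17 of 24), apoptosis genes (0.49, 17 of 23) and receptor tyrosine kinase signalling genes (0.58, 18 of 25) were also higher, with CDKN1A at 75.9-fold (29.1 to 282), DUSP4 at 42.6-fold (19.1 to 118) and PMAIP1 at 16.9-fold (13.4 to 21.6). Developmental PRC2 targets had a median of 0.35 with 14 higher and 11 lower: the forkhead gene FOXC1 was 4.52-fold higher (3.82 to 5.36) and HAND2 4.26-fold lower (3.59 to 5.09). Immediate early and heat shock genes (median 0.27) were split, 11 higher and 10 lower. With only genes of at least 5 RPKM, these lists had medians of -0.28 and -0.09. Tumour suppressors silenced by PRC2 (median 0.27) stood apart only without the filter on low values or with the libraries rescaled to the same, larger sum. Not standing apart were PRC2 subunits (-0.08), PRC1.6 and E2F6 partners (-0.16), other PRC1 subunits (-0.09), HOX genes (0.21), miR-193a targets (0.01) and stem cell genes (-0.01). The same held for G2/M genes (-0.19), estrogen response (0.39), hypoxia and glycolysis (0.04), platinum resistance and DNA repair (-0.14), nuclear oxidative phosphorylation (-0.12), cytosolic ribosomal protein (0.08), chromatin modifier (-0.17) and housekeeping genes (0.13). The PRC1 gene PCGF5 was 16.0-fold higher (9.37 to 29.5), the H3K27 demethylase gene KDM6B 3.44-fold higher (3.05 to 3.87), and PRAME 1.501-fold lower (1.26 to 1.79). In shE2F6 against shEGFP, PCGF5 was likewise 14.7-fold higher (8.73 to 26.6) and KDM6B 2.82-fold higher (2.53 to 3.15).

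Lower in shEZH2 were E2F target genes of G1/S (median -0.43, 36 of 42 lower), with UNG at 2.48-fold (2.01 to 3.08) and PCNA at 2.12-fold (1.92 to 2.34). Cholesterol synthesis genes had a median of -0.48 with 21 of 24 lower, INSIG1 by 2.49-fold (2.08 to 2.98). All 13 mitochondrially encoded genes were lower (median -0.65). WNT and Notch pathway genes (median -0.27, 18 of 25 lower) included NOTCH3 at 5.04-fold lower (4.21 to 6.08). Mesenchymal and extracellular matrix genes were lower in 16 of 26 cases, as many as in shE2F6, with a median of -0.30, with COL6A3 at 9.36-fold lower (7.43 to 12.0). The fibroblast markers, which overlap with them, did not stand apart (median -0.46). The germline list stood apart on 5 measured genes (median -0.71) but had a median of 0.07 without the filter on low values.

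Altogether 1059 of 11650 genes were at least 2-fold higher and 464 at least 2-fold lower in shEZH2 than in shEGFP, against at most 44 in the simulations. At 4-fold, 257 and 37 genes remained. Rescaling the libraries to the same, larger sum gave 2559 and 962. Without the filter on low values 13 of the 18 lists stood apart in the same direction, and the germline, developmental, mesenchymal, WNT and Notch, and immediate early lists were lost, as was the epithelial list, too small to judge, at 5 RPKM or more.

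Set against each other, the log2 ratios of both knockdowns to shEGFP had a Pearson correlation of 0.903 and a Spearman correlation of 0.863 across 11795 genes, which are not independent replicates. Because the same shEGFP library enters both ratios, unchanged libraries of these depths already gave a median Pearson correlation of 0.427. The covariance was 0.490, against a simulated median of 0.0122. Of 11332 genes measured in both comparisons, 704 were at least 2-fold higher in both knockdowns and 267 at least 2-fold lower in both. Independent lists of those sizes would share 68.7 and 17.5, and the simulations shared 3 and 4 at the median. Among the genes with the largest shared ratios were CCL5, OASL, GCG and PHLDA1 on the higher side and NID1, LOX, CCND2, SEMA6D and ACTA2 on the lower side. On the log2(RPKM + 1) scale only 1 gene was at least 2-fold from shEGFP in opposite directions, the clone-named RP11-3P17.5. It was named after its values were seen and had 17 reads in shEGFP, 20 in shEZH2 and 7 in shE2F6. By plain RPKM ratios HOXC8 also passed 2-fold in opposite directions, 2.84-fold lower (1.66 to 5.03) in shE2F6 and 3.66-fold higher (2.58 to 5.26) in shEZH2. Genes were not counted by plain ratios. With 1 control library the control cannot be split, so part of the excess may come from the shared control.

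**Figure D2:**
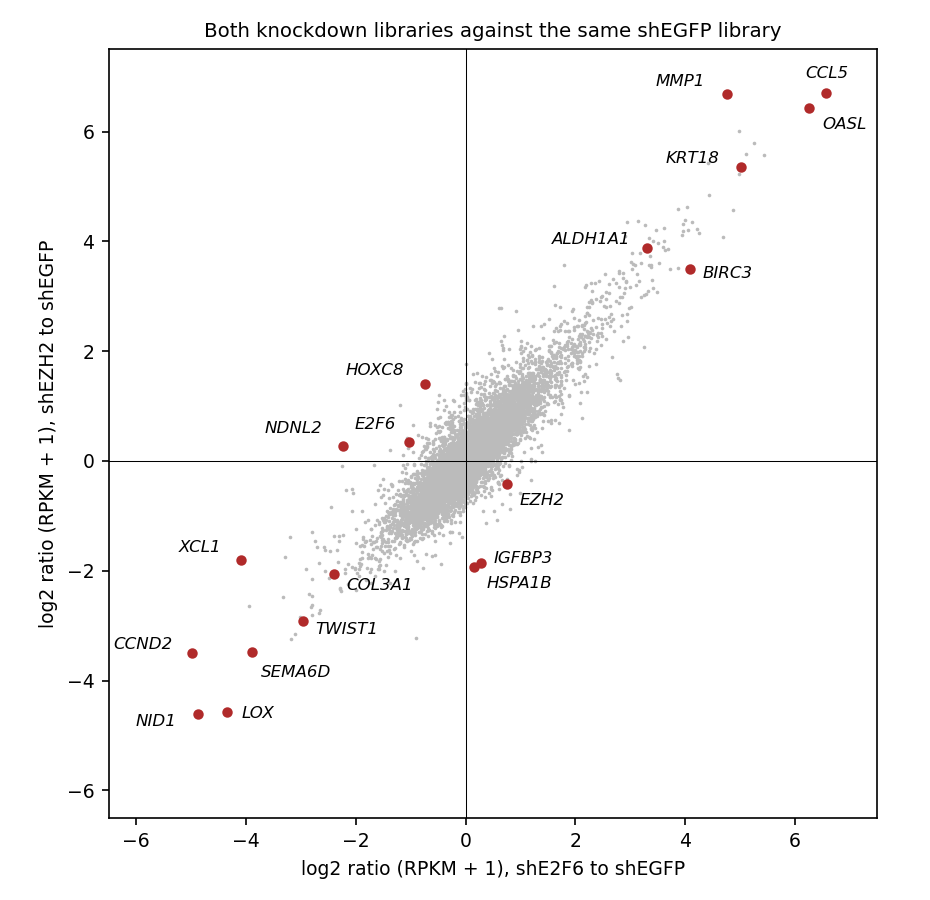
Log2 ratio of RPKM + 1 in shE2F6 (horizontal axis) and shEZH2 (vertical axis) to the same shEGFP library, 1 grey point per gene with at least 1 RPKM in any library, named genes in red. Most genes lie along the diagonal (Pearson correlation 0.903), with CCL5 and OASL at the upper end, NID1 and LOX at the lower end, and E2F6, EZH2, IGFBP3, HSPA1B and HOXC8 in the quadrants of opposite sign.

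**Figure D3:**
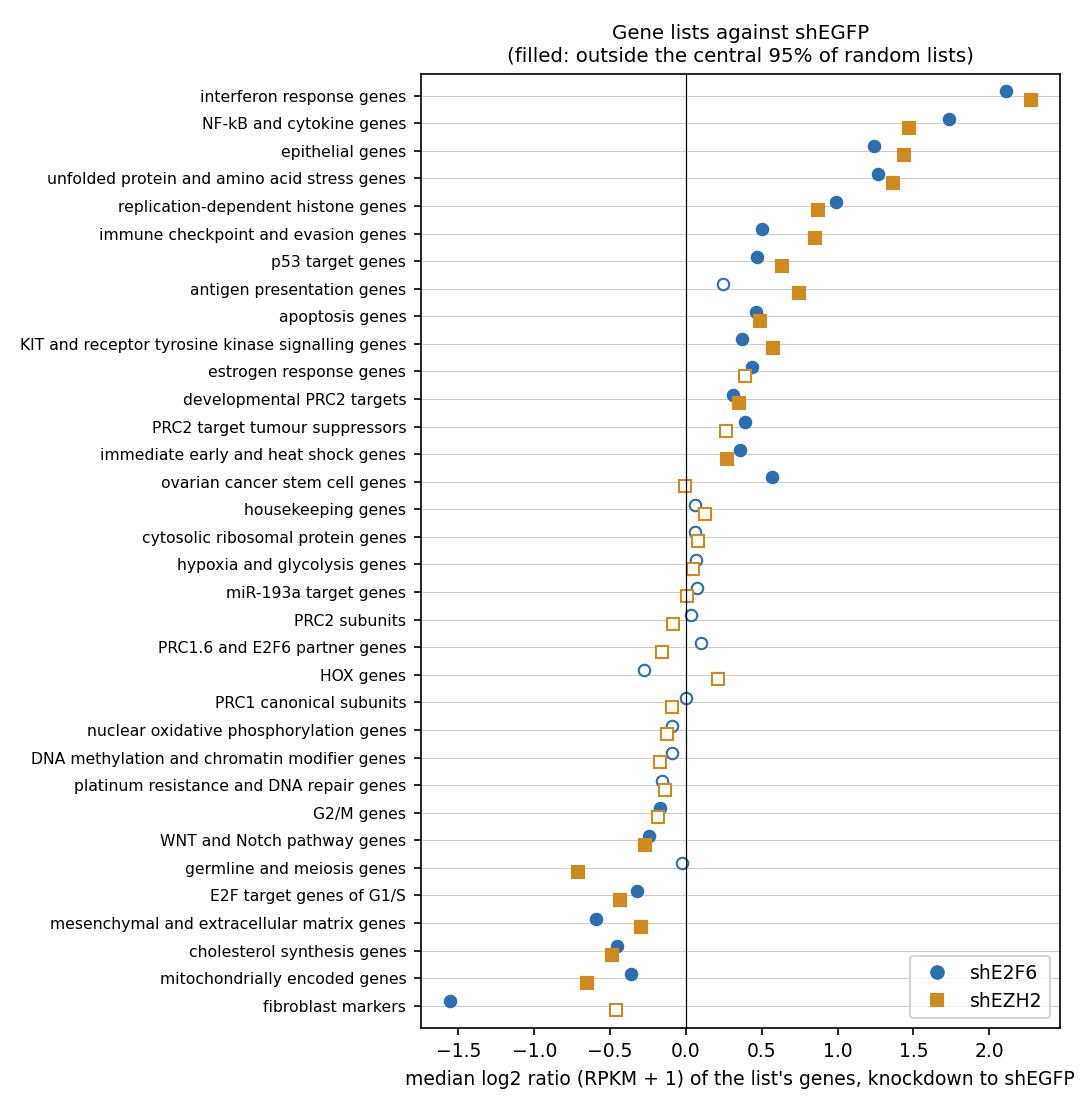
Median log2 ratio of RPKM + 1 to shEGFP (horizontal axis) for each gene list with at least 5 measured members (vertical axis), circles for shE2F6 and squares for shEZH2, filled where the median lay outside the central 95% of random lists matched on expression. Interferon response genes are highest in both, at 2.11 and 2.27, and fibroblast markers are lowest in shE2F6, at -1.56.

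The direct comparison of shE2F6 with shEZH2 leaves the control out, and the libraries were far closer: 51 of 11409 genes were at least 2-fold higher and 147 at least 2-fold lower in shE2F6. E2F6 was 3.54-fold lower (2.63 to 4.79) and EZH2 2.38-fold higher (2.05 to 2.78) in shE2F6. The growth factor binding protein gene IGFBP3 was 4.80-fold higher (4.11 to 5.63) in shE2F6, and the inducible heat shock gene HSPA1B 4.52-fold higher (3.85 to 5.34), though its reads can be shared with the near-identical HSPA1A. IL32, a proinflammatory cytokine gene, was 3.30-fold higher (2.20 to 5.14). The pseudogenes PPIAP22 and RPL15P3 ranked beside them on few reads and are uncertain. Lower in shE2F6 were XCL1 by 18.4-fold (6.57 to 71.2), the homeobox gene HOXC8 by 10.4-fold (6.38 to 17.8), NDNL2, a subunit gene of the SMC5/6 complex, by 10.2-fold (6.06 to 17.9), the secreted phosphoprotein gene SPP1 by 8.50-fold (5.22 to 14.4) and MMP1 by 3.83-fold (3.59 to 4.09). NDNL2 was also 8.20-fold lower (4.99 to 14.3) in shE2F6 than in shEGFP.

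Of 33 lists, 14 stood apart between the knockdown libraries, 3 higher and 11 lower in shE2F6, by small medians. Higher were E2F target genes of G1/S (median 0.18, 33 of 42 higher), NF-kB and cytokine genes (0.22, 11 of 17) and mitochondrially encoded genes (0.31, all 13). Interferon response genes were lower in shE2F6 (median -0.37, 37 of 43), with RSAD2 at 1.71-fold lower (1.53 to 1.90). Epithelial genes (-0.36), mesenchymal genes (-0.20), tumour suppressors silenced by PRC2 (-0.20), p53 targets (-0.19), antigen presentation (-0.20), immune checkpoint (-0.17), receptor tyrosine kinase signalling (-0.17) and unfolded protein and amino acid stress genes (-0.15) were lower as well. Immediate early and heat shock genes (-0.11) and ribosomal protein genes (-0.02) were also below random lists, but their medians were 0.01 and 0.11 after scaling to the upper quartile, and neither stood apart from random lists not matched on expression. The tumour suppressor and mesenchymal lists no longer stood apart without the filter on low values, the mesenchymal list also not after rescaling to the same, larger sum, and the immune checkpoint list not at 5 RPKM or more, where the epithelial list was too small to judge. The medians of the other lists with at least 5 measured members lay between -0.12 for HOX genes and 0.14 for PRC1.6 and E2F6 partners. The latter, with 13 of 15 higher, stood apart at a pseudocount of 0.1, at 5 RPKM or more, with the same, larger sum and with thinned reads.

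Simulated unchanged libraries gave up to 39 genes higher and 37 lower at these depths, a level that covers counting error only and not differences between cultures. The counts ran from 15 and 64 among genes of at least 5 RPKM to 395 and 914 with the same, larger sum, with 161 and 366 at a pseudocount of 0.1, 63 and 111 by upper quartile, and 21 and 74 for genes whose interval lay wholly beyond 2-fold.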

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

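All tests in this part were chosen after the result was seen. Among the named genes, 5 lay on opposite sides of shEGFP in the 2 knockdown libraries with both counting intervals clear of 1. Each group is 1 library, and the differences were not tested. The log2 ratios in shE2F6 and shEZH2 were -1.04 and 0.35 for E2F6, 0.75 and -0.41 for EZH2, 0.28 and -1.85 for IGFBP3, 0.16 and -1.94 for HSPA1B, and -0.74 and 1.41 for HOXC8.

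Both knockdown libraries differed from shEGFP in many of the same genes and in the same direction. Counting error of the shared control library is argued against, since the covariance of both log2 ratios was 0.490 and the highest of 100 simulated sets gave 0.0144. Leukocytes in the knockdown libraries are argued against as well, since 1 of 16 fixed leukocyte markers, CD68, reached 1 RPKM in both, and PTPRC, abundant in leukocytes, stood at 0.0483 RPKM in shEZH2 and 0.0230 in shE2F6. A property of the single shEGFP library, the choice of clones included, cannot be told apart from an effect common to both hairpins, because there is 1 control library: 82.0% of the variance that belongs to single libraries fell to shEGFP, as it would in either case. An effect of losing E2F6 or EZH2 stays open and untested.

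EZH2 RNA was only slightly lower in the library labelled shEZH2. A swap of labels with shE2F6 is argued against, since E2F6 was 1.33-fold higher there than in shEGFP (1.05 to 1.69). Lower G1/S gene RNA in the same library could account for the EZH2 value: EZH2 lay at percentile 50 of 42 fixed G1/S genes, whose median log2 ratio was -0.43. A small loss through the hairpin could give the same percentile, so it does not decide between them. In shE2F6 against shEGFP, EZH2 did not follow these genes, with a log2 ratio of 0.75 beside their median of -0.32. Loss through the hairpin stays open, and EZH2 protein was not analysed here.

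EZH2 RNA was higher in shE2F6 than in shEGFP. A rise of the G1/S genes as a group is argued against, since EZH2 lay at percentile 97.6 of the 42 genes while their median was -0.32. The scaling of the libraries is argued against too, since the lowest log2 ratio over the 3 other scalings was 0.72. Relief of repression by E2F6 is a hypothesis that was not tested.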

How the results depend on the processing

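Reads thinned to the shallowest library and the count by interval beyond 2-fold were alternatives chosen after seeing the data. The log2 ratios of E2F6 and EZH2 moved by no more than 0.5 of the width of their counting intervals under every alternative that applied, and no named gene reversed, with 2015 values the same and 310 moved. The numbers of lists standing apart stayed within 1.5 times in all 27 cases, and of their medians 433 were the same, 33 moved and 10 reversed. The correlation stayed within 0.05 of 0.903 in 7 of 8 alternatives and was 0.840 after rescaling to a common sum. Of the gene counts, 36 were the same and 24 moved. Counts are given as higher and lower. For shE2F6 against shEGFP (846 and 428), they were 494 and 282 at 5 RPKM or more, 1822 and 976 with the common sum, 219 and 55 at 4-fold, with 823 lower at a pseudocount of 0.1. For shEZH2 against shEGFP (1059 and 464), they were 630 and 309, 2559 and 962, and 257 and 37, with 910 lower at a pseudocount of 0.1. For shE2F6 against shEZH2 (51 and 147), they were 15 and 64, 395 and 914, and 3 and 7, with 161 and 366 at a pseudocount of 0.1 and 21 and 74 by interval. Stricter thresholds count fewer genes by construction. Dropping the filter on low values cannot change a 2-fold count at a pseudocount of 1, so those counts were the same by construction too. The common sum changes both the weight of the pseudocount and the relative scaling, and these were not separated. Upper quartile scaling gave 63 and 111 for shE2F6 against shEZH2. Reversed medians at 5 RPKM or more were -0.20 for PRC2 target tumour suppressors and -0.46 for developmental PRC2 targets in shE2F6 against shEGFP, and -0.28 for developmental PRC2 targets and -0.09 for immediate early and heat shock genes in shEZH2 against shEGFP. Without a filter, stem cell genes had -0.0031 in shE2F6 against shEGFP, and germline genes 0.070 and immediate early and heat shock genes -0.091 in shEZH2 against shEGFP. Germline genes had 0.54 with the common sum, and by upper quartile ribosomal protein genes had 0.11 and immediate early and heat shock genes 0.014 in shE2F6 against shEZH2. For the other moved counts, the reversed medians and the correlation the cause was not tested. Lists that stood apart only under an alternative were, against shEGFP in shE2F6, platinum resistance and DNA repair, antigen presentation and HOX genes, and in shEZH2 estrogen response and stem cell genes, PRC2 target tumour suppressors and fibroblast and leukocyte markers. Between the knockdowns they were PRC1.6 and E2F6 partners, HOX genes, histone genes and fibroblast markers. Filters gave no new value for named genes. No paired analysis was possible because each group holds 1 library, nor could a library be left out. Depth limits shEZH2 most, which had 4871295 mapped reads.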

Other observations

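The genes in this part were chosen after their values were seen, apart from IFNL1, HSPA1B and ATF3. The interferon genes IFNB1 and IFNL1 to IFNL3 had reads in both knockdown libraries and none in shEGFP. IFNB1, the beta interferon gene, had 26 reads in shEZH2 and 51 in shE2F6, at least 16.0-fold and 15.0-fold above the floor of shEGFP, with intervals from 12.1 and 11.7. The type III interferon genes IFNL2 and IFNL3 were at least 24.7-fold and 21.6-fold higher in shEZH2, with intervals from 19.2 and 16.6, and at least 17.9-fold and 14.4-fold higher in shE2F6, with intervals from 14.1 and 11.3. IFNL1 was at least 93.8-fold and 78.1-fold higher, with intervals from 75.3 and 63.1, though these copies share sequence. HMOX1, the inducible heme oxygenase gene, was 36.3-fold higher (29.4 to 45.4) in shE2F6 than in shEGFP and 29.4-fold higher (23.7 to 36.9) in shEZH2. The ferritin light chain gene FTL was 4.94-fold (4.76 to 5.13) and 5.22-fold (5.02 to 5.44) higher, and SLC7A11, the cystine transporter gene, 15.7-fold (12.5 to 19.9) and 24.6-fold (19.6 to 31.2). Of further genes of the oxidative stress response, TXNRD1 was 3.39-fold higher in shE2F6 and 4.60-fold in shEZH2, SQSTM1 5.86-fold and 4.58-fold, whereas NQO1 and GCLM were close to shEGFP, NQO1 at 1.14-fold and 1.02-fold and GCLM at 1.23-fold in both.

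A few chaperone genes, picked for this pattern, were lower in shEZH2 than in both other libraries. The fixed list of immediate early and heat shock genes was split in shEZH2 against shEGFP, 11 higher and 10 lower, with a median log2 ratio of 0.27. That median was -0.091 without the filter on low values and at 5 RPKM or more. The chaperone gene HSPA5 was 2.71-fold higher in shEZH2 than in shEGFP. The constitutive chaperone gene HSPA8 stood at 533 RPKM in shEGFP, 204 in shEZH2 and 509 in shE2F6, beside HSPA1B at 54.3, 13.4 and 60.7. The cochaperone gene DNAJB1 was 2.10-fold higher (1.80 to 2.47) in shE2F6 than in shEZH2, and its shEZH2 level was 0.386 of that in shEGFP (0.329 to 0.449). ATF3, a stress-induced transcription factor gene, was higher in shE2F6 than in shEZH2 by 1.53-fold (1.42 to 1.65).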
